A study of Mus musculus with 12 samples.

How the data were processed

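Expression was measured on 12 single-colour Affymetrix arrays of total RNA from the mouse natural killer (NK) cell lines KY-1 and KY-2. Both lines lack p53 and were grown with 200 U/mL human IL-15, per the labels. The cells carried a vector for green fluorescent protein (GFP) alone or for GFP joined through a P2A peptide to FLAG-tagged Myb, and GFP-positive cells were sorted before RNA extraction, per the labels' protocols. KY-1 had 3 GFP arrays and 4 Myb arrays, and KY-2 had 2 GFP arrays and 3 Myb arrays.

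The deposited values are log2 expression summaries per probe set, and Partek and RMA are named in the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises probes. Its options, the software versions and any filters are not given in the sources used here. Values ran from 1.49 to 13.96 on the log2 scale, and array medians lay between 5.31 and 5.42. The number of arrays limits the precision. The table carries no detection calls, so a low value has no measured background beside it.

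Of 35556 probe sets, 21789 were paired with 1 gene symbol, 1621 with several, and 12146 were not listed in the annotation used. Symbols were checked through Entrez identifiers against the RefSeq gene table of GRCm38.p6, which changed 0 of them, and 91 probe sets kept the annotation's symbol because their identifier was not found there. For the 999 genes with more than 1 such probe set, the brightest over the 12 arrays was used. This left 19938 genes, all tested without a filter on dim signals. Probe sets can read near-identical family members, which makes values of the Klrb1, Klra, Klri, granzyme, Lilr, Bcl2a1 and olfactory receptor genes uncertain as to the member.

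Arrays within each group were compared before averaging. Over 10624 probe sets with a mean above 7, KY-1 GFP arrays 1 and 2 and KY-1 Myb arrays 3 and 4 had robust SDs of their log2 differences between 0.0434 and 0.0469. All other pairs within a group lay between 0.102 and 0.172. Each close pair was averaged and counted as 1 sample, since the arrays differed by less than the spread of separate samples, although the labels do not say that they share RNA. This was decided from the spread, before any count of genes was seen. This gave 10 replicates, 2 for each GFP group and 3 for each Myb group. The design fixed before the data were examined had treated all 12 arrays as separate replicates, and its counts are given beside the main ones. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

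Gene tests used limma 3.58.1 in R 4.3.3, with 1 linear model of the 4 group means (lmFit, contrasts.fit and eBayes) and Benjamini-Hochberg adjustment over all genes, at a threshold of 0.05. The contrasts were Myb minus GFP in KY-1, in KY-2 and averaged with equal weight, the difference between the Myb effects of the lines, and KY-2 minus KY-1 with the GFP vector. The first 2 contrasts share no arrays but share 1 residual variance per gene. Fitted values have 6 residual degrees of freedom and a prior of 4.89. Errors on log2 differences are standard errors (SE) of the model, and errors on group levels are SDs over replicates.

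A total of 36 gene lists, covering NK cell programmes, other blood cell types, cell division, metabolism, signalling and reported targets, were written before the data were examined. They held 789 entries, of which 724 were tested, and some genes stand in several lists. Shifts of a list were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. An estimated correlation and the directional fry test were alternatives. Member counts came from the gene test, adjusted over all genes and, where stated, adjusted over the list alone.

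Genes were named by a rule set in advance. Myb came first, then the 8 highest and 8 lowest changes of the averaged contrast with the same sign in both lines, 5 and 5 for each line and for the difference between lines, and 8 and 8 between the lines with GFP. Predicted genes and small RNA genes were left out of these ranks. Up to 4 members with the smallest p were named for each list described.

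Alternatives were a filter on dim genes, a second quantile normalization, median centring, the mean of a gene's probe sets, trended and robust moderation, array weights, fits of only the arrays compared, a threshold of 1.5-fold, and leaving out each replicate. The fit of all 12 arrays as separate replicates was the design fixed beforehand, and averaging the close pairs was chosen after the arrays were compared. A block of replicate number was planned too, but its fit on all 12 arrays was chosen after averaging, because the averaged pairs cross replicate numbers. A block of 2 sets of KY-1 arrays, the test of lists on the difference between lines and the overlap of calls from each line fitted alone were added after the data were seen. The gene tests were checked on simulated data, drawn 10 times for 19938 genes with 200 changed genes each. The noise was normal, independent between genes and replicates, and had the model's own variances, so recovery in the real data may be lower. For the KY-1 comparison 79% of 1.5-fold changes and 99.7% of 2-fold changes were recovered, and for the averaged comparison 97.6% of 1.5-fold changes. For the difference between lines 30.7% of 1.5-fold changes and 92.1% of 2-fold changes were recovered. Figures were drawn with matplotlib 3.10.9.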

Results

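KY-1 and KY-2 are mouse NK cell lines, lymphocytes of the innate immune system that kill target cells and secrete cytokines. Transcript levels were measured after transduction with a GFP vector or a vector for GFP and Myb, a transcription factor of blood progenitors. The series addressed how raised Myb changes expression in NK cells, as part of a study of microRNA-15/16, Myb and NK cell maturation. There were 3 GFP and 4 Myb arrays of KY-1 and 2 GFP and 3 Myb arrays of KY-2. Among the KY-1 arrays, 2 pairs differed by less than the spread of separate samples and were each counted as 1 sample. That left 2 GFP and 3 Myb replicates per line.

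Myb (probe set 10368199) was higher with the Myb vector in both lines, which fits the labels of all 12 arrays. In KY-1 the level went from 7.99 ± 0.07 (SD, n = 2) on the log2 scale to 9.57 ± 0.02 (SD, n = 3), a 2.99-fold difference. In KY-2 it went from 5.05 ± 0.07 (SD, n = 2) to 9.74 ± 0.07 (SD, n = 3), and the GFP level lay below the array medians. The log2 differences were 1.58 ± 0.08 (SE, limma adjusted p = 3.89e-06) and 4.69 ± 0.08 (SE, limma adjusted p = 1.06e-10). The lines thus started from different Myb levels with GFP and reached similar levels with the vector, and the rise was larger in KY-2 by 3.11 ± 0.11 (SE, limma adjusted p = 3.84e-07). The probe set's value was not split into native and vector-derived transcript.

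**Figure D1:**
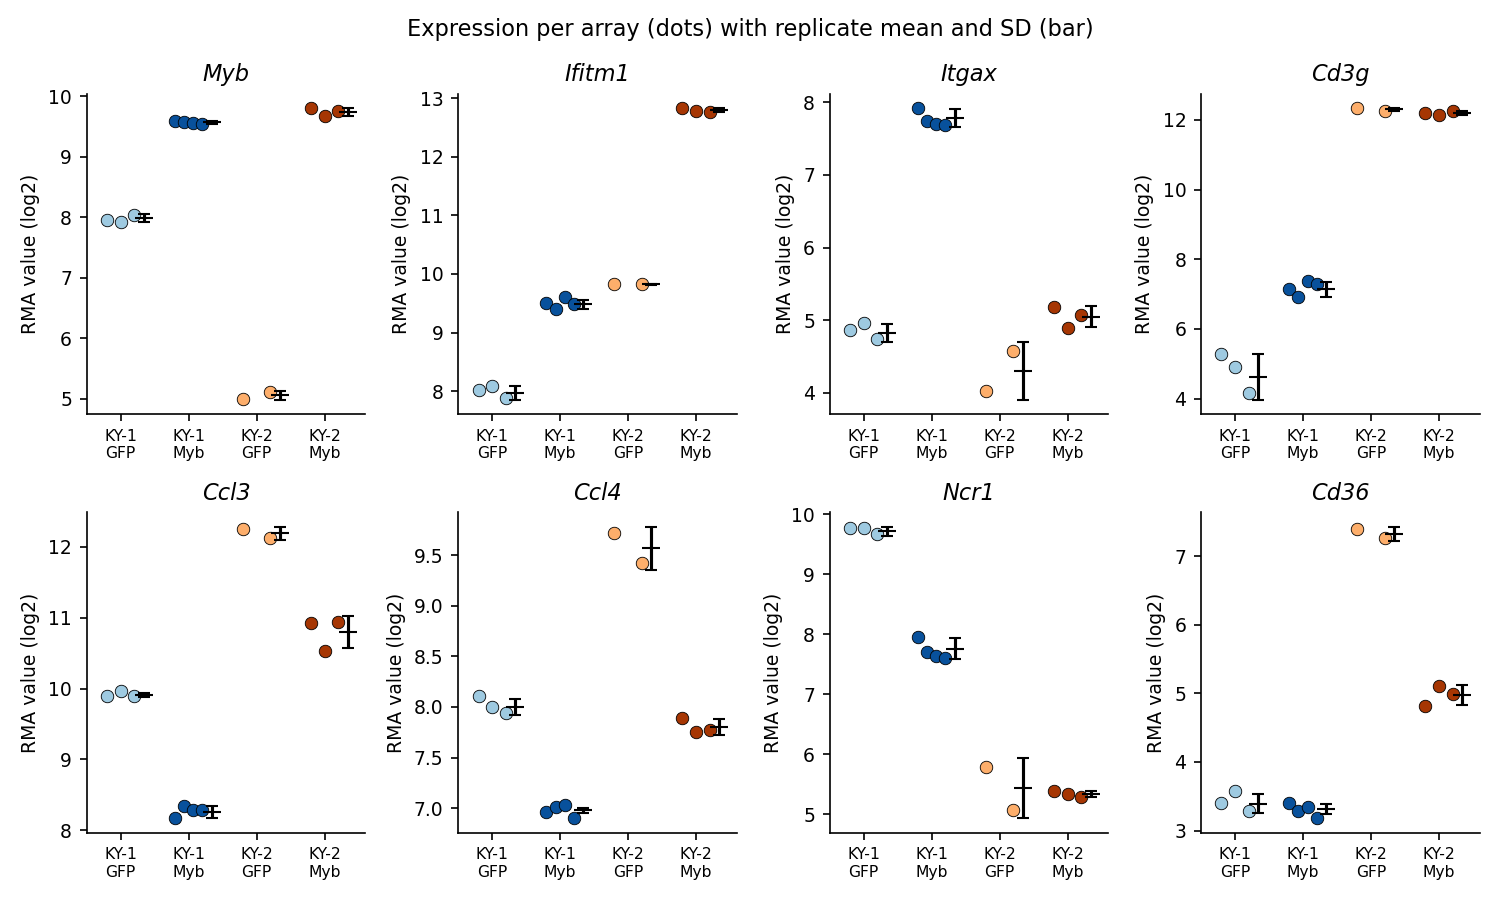
Log2 RMA value of 8 genes on each of the 12 arrays (dots), with the mean and SD of the replicates beside them (bars), for the KY-1 and KY-2 lines with the GFP or Myb vector. Myb and Ifitm1 were higher and Ccl3 and Ccl4 lower with the Myb vector in both lines, while Itgax, Cd3g and Ncr1 changed mainly in KY-1 and Cd36 in KY-2. With GFP, Ncr1 in KY-2 lay near and Cd36 in KY-1 below the array medians, where a fall would be hard to see.

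Averaged over both lines, the genes that rose most beside Myb were Ifitm1, an interferon-inducible membrane protein, by 2.24 ± 0.06 log2 (SE, 4.73-fold), and Itgax, the integrin CD11c, by 1.85 ± 0.11. Tacr1, the substance P receptor, rose by 1.71, Mgst2 by 1.68, Plac8 by 1.66, Heg1 by 1.44 and Il18, a cytokine that activates NK cells, by 1.41. The chemokine genes Ccl3 and Ccl4 fell by 1.52 ± 0.09 and 1.39 ± 0.07. The NK receptor gene Klrb1a fell by 1.37 and the interleukin-21 receptor gene Il21r by 1.26. Cd36, a fatty acid transporter, fell by 1.22, Sema6d by 1.18, the inhibitory receptor gene Lilrb4a by 1.15 and Xlr by 1.13. Limma adjusted p-values of these genes were at most 0.000112 (n = 4 GFP and 6 Myb replicates). For 15 of the 16 genes named here the Myb arrays lay entirely above or below the GFP arrays in each line. Chance gives 20% per line for 2 against 3 replicates, and less for the single KY-1 arrays counted here, if a gene is taken without regard to its values. That does not hold for genes chosen by their change. The exception was Cd36, which changed by -0.08 in KY-1 (adjusted p = 0.871), where its GFP level of 3.39 lay below the array medians. Plac8 (3.795 to 4.812) and Xlr (4.671 to 3.107) lay below the medians in KY-1 with both vectors, so the sizes of those changes are uncertain.

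In total 303 genes rose and 316 fell at a limma adjusted p under 0.05, or 3.1% of 19938 genes, and 142 of them changed at least 1.5-fold. The balance turned to 361 higher and 302 lower after a second quantile normalization, 297 and 263 after median centring and 184 and 130 without KY-2 GFP replicate 1. With all 12 arrays as separate replicates the total was 1143, among them all 619, and trended moderation gave 1043. The total fell to 358 without the averaged KY-1 GFP arrays 1 and 2, to 368 without KY-1 GFP replicate 3 and to 314 without KY-2 GFP replicate 1.

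NK receptors and adaptors were the list with the smallest p in the averaged contrast. Of 30 tested members 1 rose and 8 fell, and 1 rose and 15 fell when adjusted over the list alone. Cd226, an activating receptor also called DNAM-1, fell by 0.91 ± 0.07 log2 in the average and in both lines. Crtam, an adhesion receptor, fell by 0.96 ± 0.08, from KY-2 alone (0.03 in KY-1, adjusted p = 0.961, and -1.96 in KY-2). Its GFP level was 4.64 in KY-1, below the array medians, where a fall would be hard to see, and 8.02 in KY-2. Fcgr3, the Fc receptor CD16, fell by 0.69 ± 0.06 and Klrb1a by 1.37 ± 0.12. The list's mean change was -0.276 (camera adjusted p = 1.68e-12), with an adjusted p = 0.132 with an estimated correlation.

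Of 12 chemokine genes 0 rose and 4 fell, and 5 fell when adjusted over the list alone. Beside Ccl3 and Ccl4, the lymphotactin gene Xcl1 fell by 0.68 ± 0.06 and Ccl1 by 0.66 ± 0.09, the last mainly in KY-2 (-0.19 in KY-1, adjusted p = 0.655). The mean change was -0.428 (camera adjusted p = 3.64e-08), with an adjusted p = 0.0839 with an estimated correlation.

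Immediate early and activation genes, which respond within minutes to receptor signals, had 0 members that rose and 4 of 22 that fell, and 10 fell when adjusted over the list alone. Egr2 fell by 0.79 ± 0.10, Jun by 0.53 ± 0.08, Nr4a2 by 0.41 ± 0.07 and Btg2 by 0.39 ± 0.08. The mean change was -0.184 (camera adjusted p = 1.11e-05), with an adjusted p = 0.139 with an estimated correlation. In KY-1 alone the list did not pass (0 rose and 1 fell, also adjusted over the list alone; camera adjusted p = 0.35).

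Of 22 NK cytotoxic effector genes 0 rose and 5 fell; adjusted over the list alone, 1 rose and 9 fell. Granzyme gene Gzmd fell by 0.79 ± 0.07, the interferon gamma gene Ifng by 0.71 ± 0.07, the Fas ligand gene Fasl by 0.37 ± 0.07 and the perforin gene Prf1 by 0.32 ± 0.06. The mean change was -0.185 (camera adjusted p = 1.46e-05), with an adjusted p = 0.341 with an estimated correlation. In KY-1 alone the list did not pass (1 rose and 1 fell, or 1 and 3 adjusted over the list alone; camera adjusted p = 0.323). There Gzma rose by 0.54 ± 0.08 (limma adjusted p = 0.00742), Ifng fell by 0.54 ± 0.09, and Prf1, lower in KY-2, was at 0.18 ± 0.09 (limma adjusted p = 0.503). The granzyme genes Gzmb and Gzmc, among the brightest genes on the arrays, had averaged changes of -0.04 and -0.03 and were not called.

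**Figure D2:**
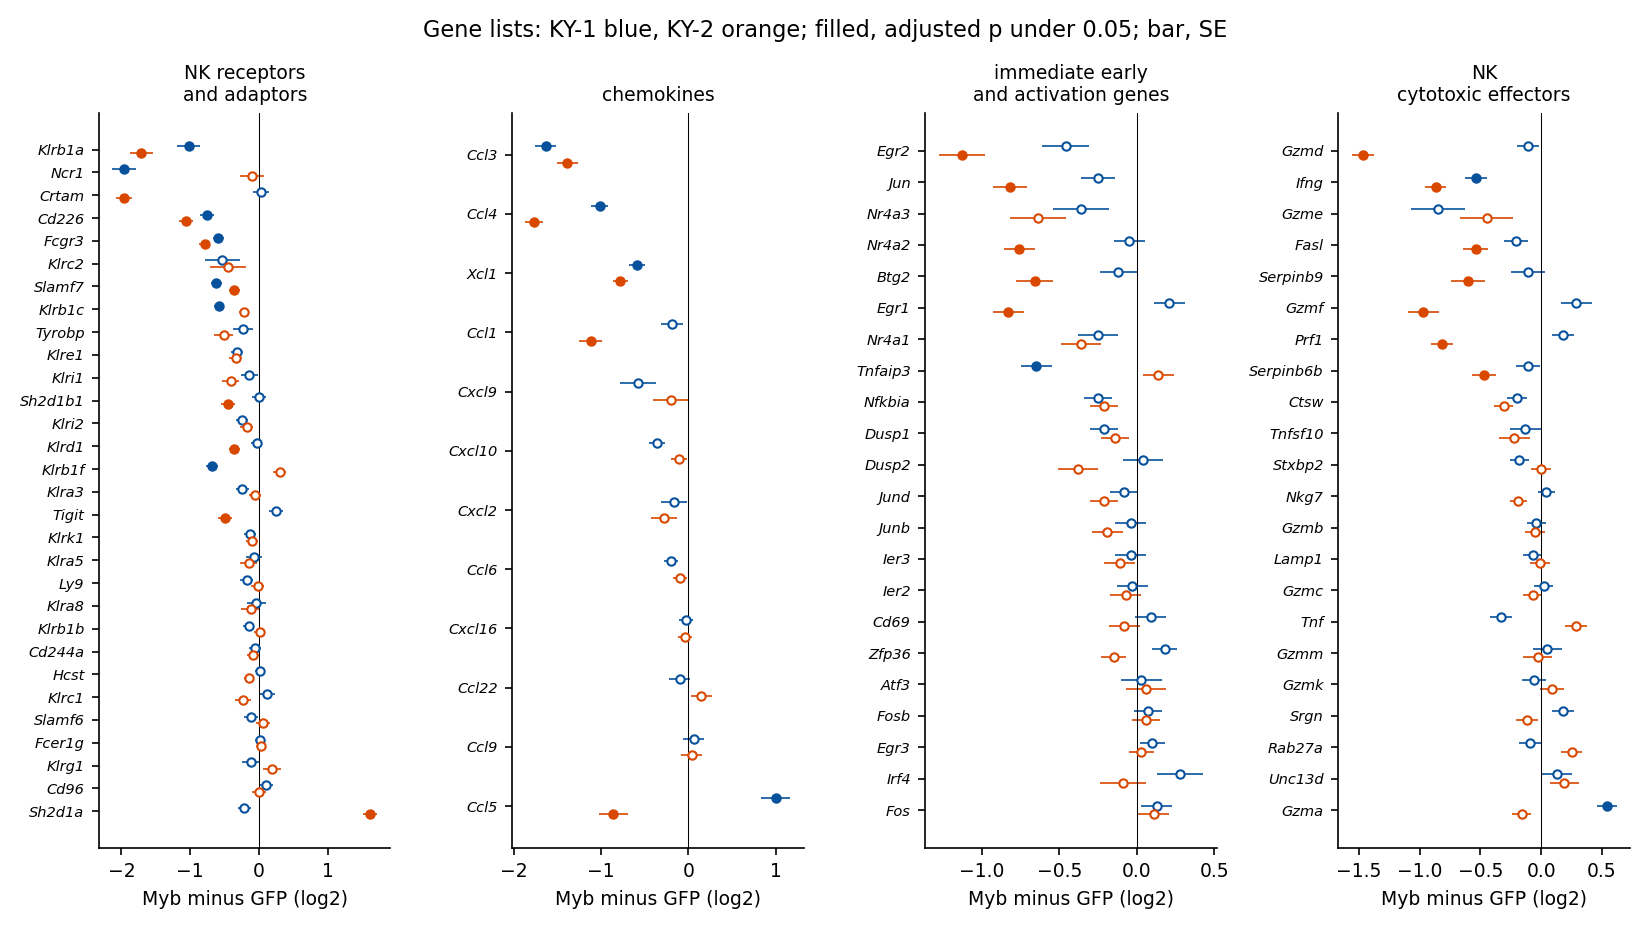
Log2 difference between Myb and GFP vectors for each tested member of 4 gene lists, in KY-1 (blue) and KY-2 (orange), with SE bars and filled points for a limma adjusted p under 0.05. Ccl3, Ccl4 and Xcl1 fell in both lines, Crtam and Gzmd were lower in KY-2 alone among calls, and Ccl5 moved in opposite directions. Crtam in KY-1 lay below the array medians with GFP.

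The other 32 lists did not pass camera in the averaged contrast. Mature NK cell markers had an adjusted p = 0.888, with Itgax higher and Ccl3 and Serpinb9b lower, the last call lost in 12 of 19 alternative settings (1 rose and 2 fell of 19; 3 and 4 adjusted over the list alone). Their median was -0.001, the mean 0.006 and the camera direction downward. The means of the lines had opposite signs, but the medians were -0.038 in KY-1 and -0.051 in KY-2. In each line 8 members had a positive and 11 a negative change. By limma 3 were higher and 1 lower in KY-1 (mean 0.136, camera adjusted p = 0.513). In KY-2 2 were higher and 3 lower (mean -0.124, camera adjusted p = 0.126). The immature NK cell markers had an adjusted p = 0.411, with Xcl1 and Cxcr3 lower (0 rose and 2 fell of 20; 0 and 3 adjusted over the list alone). Among 33 tested genes reported as Myb targets 3 rose and 1 fell (4 and 1 adjusted over the list alone). They were Cxcr4, a chemokine receptor, which rose by 1.10 ± 0.08, Ada by 0.40 ± 0.07 and Cebpb by 0.36 ± 0.08, and Birc3, which fell by 0.31 ± 0.06 (list adjusted p = 0.118). Among 23 tested genes reported as microRNA-15/16 targets only Pdcd4 passed, also when adjusted over the list alone, and it fell by 0.67 ± 0.06 (list adjusted p = 0.922; median 0.006, mean -0.007, camera direction downward). By limma 0 of 28 G1/S and 0 of 29 G2/M genes were called, also when adjusted over the list alone, and 3 of each had an unadjusted p under 0.05 (list adjusted p = 0.44 and 0.286). Markers of other cell types gave camera adjusted p = 0.718 for T cells, 0.922 for B cells (median 0.036, mean 0.004, camera direction downward), 0.459 for myeloid cells, 0.44 for mast cells and basophils and 0.922 for erythroid cells and megakaryocytes. In KY-1 with GFP few of these markers stood above a log2 level of 8. They were 3 of 18, 1 of 16, 0 of 21, 2 of 17 and 2 of 14 in the same order, so the tests cover mostly genes of low signal.

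In KY-1 alone, Itgax rose by 2.96 ± 0.15 log2, Cd3g, a chain of the T cell receptor complex, by 2.52 ± 0.21, and the lectin-like receptor gene Klrh1 by 2.52 ± 0.12. Nt5e, the ectoenzyme CD73, rose by 1.87 ± 0.10 and the mast cell and basophil protease gene Mcpt8 by 1.76 ± 0.17. The activating receptor gene Ncr1, which encodes NKp46, fell by 1.96 ± 0.17, Ccl3 by 1.64 ± 0.12, Xlr by 1.56 ± 0.13, B3galt2 by 1.36 ± 0.15 and Timp2, a metalloproteinase inhibitor, by 1.31 ± 0.13. Limma adjusted p-values were at most 0.00121 (n = 2 GFP and 3 Myb replicates), and for each of these genes and Myb the arrays of both vectors did not overlap, as their choice by size of change favours. Xlr went from 4.67 to 3.11, below the array medians with both vectors, so the size of its fall is uncertain.

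In KY-1 122 genes rose and 122 fell, 244 in all or 1.22% of genes, with 134 changed at least 1.5-fold. Median centring of the arrays gave 139 higher and 83 lower. The total was 823 with all 12 arrays as separate replicates, 503 with trended moderation, 414 among brighter genes and 106 with KY-1 arrays alone. It fell to between 72 and 142 on leaving out any 1 of the 5 KY-1 replicates.

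Of the NK receptors and adaptors 0 rose and 7 of 30 fell in KY-1 (0 and 8 adjusted over the list alone). Ncr1 was followed by Klrb1c, the receptor NK1.1, which fell by 0.58 ± 0.07, Klrb1f by 0.68 ± 0.09 and Slamf7 by 0.62 ± 0.08 (camera adjusted p = 1.6e-08; adjusted p = 0.301 with an estimated correlation). Of the chemokines 1 rose and 3 of 12 fell (1 and 5 adjusted over the list alone). Ccl4 fell by 1.02 ± 0.10 and Xcl1 by 0.59 ± 0.09, while Ccl5, also called RANTES, rose from 8.19 to 9.19 (SE of the difference 0.17) (camera adjusted p = 7.02e-05; adjusted p = 0.291 with an estimated correlation). The G2/M genes shifted lower as a list by a mean of -0.105 with 0 members called by limma (2 fell when adjusted over the list alone, 3 at an unadjusted p under 0.05), among them Mki67 at -0.31 ± 0.08 and Cenpf at -0.30 ± 0.07 (camera adjusted p = 0.000221, and 0.742 with an estimated correlation). Fry did not call the G2/M list (adjusted p = 0.098), and its mean ran from -0.135 to -0.062 over the alternative settings. Ribosome biogenesis genes, among them Mybbp1a at 0.22 ± 0.08 and Nop2 at 0.21 ± 0.08, shifted higher by a mean of 0.070 with 0 of 25 called by limma, also adjusted over the list alone, and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.043; adjusted p = 0.742 with an estimated correlation), and that call was lost in 12 of 20 alternative settings.

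In KY-2 alone, the genes that rose most after Myb were Ambn, which encodes an enamel matrix protein, by 3.30 ± 0.12 log2, Ifitm1 by 2.97 ± 0.08, Tacr1 by 2.94 ± 0.09 and the tubulin gene Tuba8 by 2.43 ± 0.12. Cd36 fell by 2.36 ± 0.10, Tmem273 by 2.32 ± 0.16, Plek, the platelet and leukocyte protein pleckstrin, by 1.97 ± 0.10, Crtam by 1.96 ± 0.12, and the olfactory receptor gene Olfr803 fell by 1.93 ± 0.28. Limma adjusted p-values were at most 0.0029 (n = 2 GFP and 3 Myb replicates), and the arrays of both vectors did not overlap for any of these 10 genes, Myb included, which were also chosen by size of change.

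In KY-2 256 genes rose and 309 fell, 565 in all or 2.83% of genes, with 282 changed at least 1.5-fold. Median centring gave 211 higher and 316 lower, and the balance turned to 102 and 80 without KY-2 GFP replicate 1. With all 12 arrays as separate replicates the total was 759, with trended moderation 897 and with KY-2 arrays alone 346. It was 182 without KY-2 GFP replicate 1, 284 without GFP replicate 2 and 367 without Myb replicate 3.

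In KY-2 1 NK receptor or adaptor rose and 8 of 30 fell (2 and 12 adjusted over the list alone). The signalling adaptor gene Sh2d1a, or SAP, rose by 1.62 ± 0.10, while Crtam, Cd226 (-1.06 ± 0.10) and Klrb1a (-1.71 ± 0.17) were lower (camera adjusted p = 1.37e-07; adjusted p = 0.221 with an estimated correlation). Of 12 chemokines 5 fell and 0 rose, also when adjusted over the list alone, with Ccl4 at -1.77 ± 0.10, Ccl1 at -1.12 ± 0.13 and Xcl1 at -0.78 ± 0.09 (camera adjusted p = 1.37e-07; adjusted p = 0.0983 with an estimated correlation). Of 22 immediate early genes 5 fell and 0 rose (6 and 0 adjusted over the list alone), with Egr2 at -1.13 ± 0.15, Egr1 at -0.83 ± 0.10 and Jun at -0.82 ± 0.11 (camera adjusted p = 3.05e-07; adjusted p = 0.119 with an estimated correlation). Of 22 cytotoxic effectors 7 fell and 0 rose (9 and 2 adjusted over the list alone), with Gzmd at -1.47 ± 0.09, Ifng at -0.87 ± 0.09 and Prf1 at -0.82 ± 0.09 (camera adjusted p = 5.33e-07; adjusted p = 0.221 with an estimated correlation).

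A further 5 lists passed camera in KY-2 with smaller shifts. Amino acid response and transport genes were higher by a mean of 0.175, with Asns, asparagine synthetase, at 0.41 ± 0.08 and Slc7a5 at 0.49 ± 0.11 the 2 calls among 19, or 4 adjusted over the list alone (adjusted p = 0.000264; adjusted p = 0.221 with an estimated correlation). G1/S genes were higher by a mean of 0.098 with 0 of 28 called by limma, also adjusted over the list alone, and 3 at an unadjusted p under 0.05, among them Mcm2 at 0.30 ± 0.09 (adjusted p = 0.00522; adjusted p = 0.408 with an estimated correlation; lost without KY-2 Myb replicate 2, adjusted p = 0.1). Checkpoint and costimulatory receptors had 1 call of 21 (2 adjusted over the list alone), Tigit at -0.49 ± 0.10, and reported p53 targets 2 of 20 (4 adjusted over the list alone), Btg2 at -0.66 ± 0.12 and Sesn1 at -0.37 ± 0.08, in lines that lack p53 (both adjusted p = 0.0218; adjusted p = 0.264 with an estimated correlation). NK lineage transcription factors had 2 higher and 3 lower of 19 (3 and 5 adjusted over the list alone), with Ikzf2 at 0.79 ± 0.09, Ikzf3 at -0.87 ± 0.11 and Ets1 at -0.79 ± 0.13 (adjusted p = 0.0368; adjusted p = 0.408 with an estimated correlation). The checkpoint, p53 and transcription factor calls were each lost on leaving out at least 1 KY-2 replicate.

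The Myb effects of both lines were compared gene by gene. Calls shared by both lines included Myb, Ifitm1, Heg1, Il18, Kcnn4 and Napsa among 49 genes that rose, against 1.57 from the product of the list sizes. Ccl3, Ccl4, Klrb1a, Il21r and Sema6d were among 41 genes that fell in both, against 1.89, and 9 were called in opposite directions, against 3.46. The fit of all groups gives both contrasts 1 residual variance per gene, which favours the same genes in both, so these products are not the overlap without an effect. With each line fitted alone 14 genes rose in both against 0.441 (Fisher's exact test p = 8e-18, two-sided, across genes), 17 fell in both against 0.478 (p = 1.98e-22) and 2 were opposite against 0.92. The 9 opposite genes were Csn3, Igf1, Cd7, Ccl5, Castor2, Zbtb32 and Myh10, higher in KY-1 and lower in KY-2, and Clec2i and Fads2, the reverse; Kcnn4, Napsa and, Csn3 apart, these 9 genes were named after their values were seen. Across all 19938 genes the log2 differences correlated weakly between lines (Pearson r = 0.197, Spearman rho = 0.105), and 52.7% had the same sign. Among the 710 genes called in either line r was 0.362 and 69.6% had the same sign. Genes are not independent replicates, and these values describe the gene sets only.

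**Figure D3:**
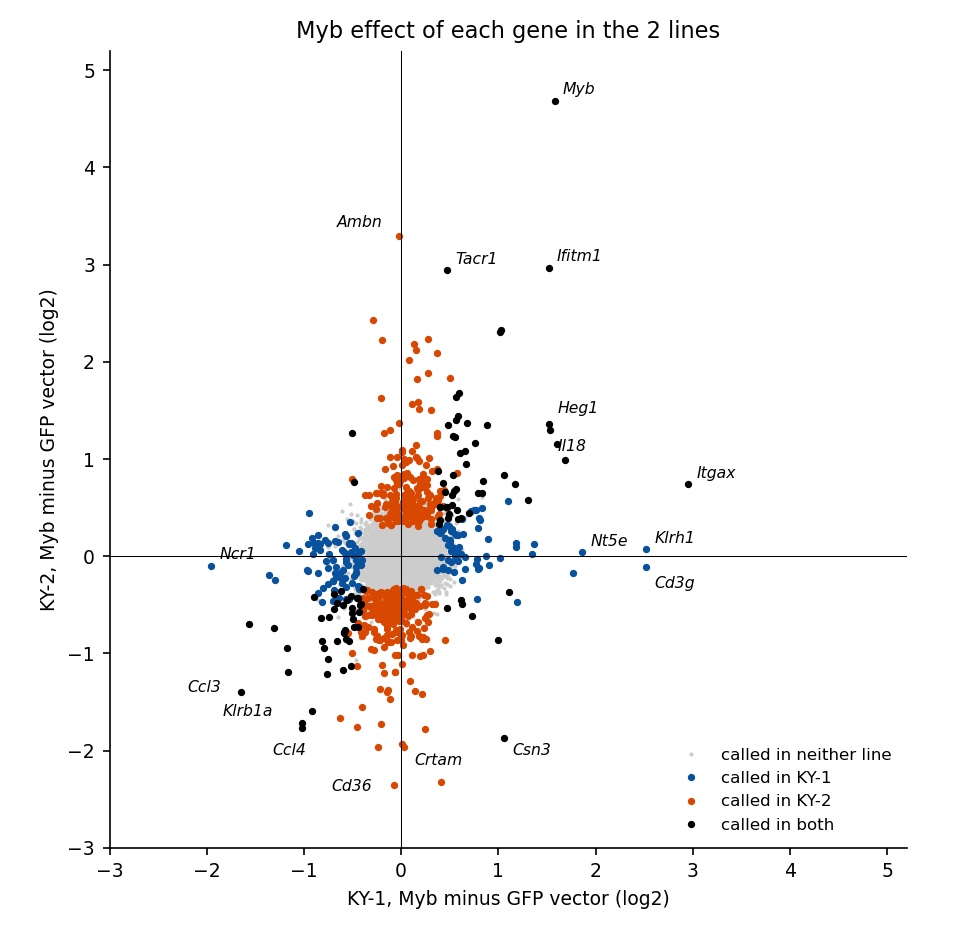
Each point is 1 of 19938 genes, with the log2 difference between Myb and GFP vectors in KY-1 on the x axis and in KY-2 on the y axis, coloured by the line in which the limma adjusted p was under 0.05. Myb, Ifitm1 and Itgax lie in the upper right and Ccl3 and Ccl4 in the lower left, while Ambn and Cd36 follow the y axis and Ncr1, Klrh1 and Cd3g the x axis.

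The Myb effect differed between lines for 168 genes, 92 with the more positive effect in KY-2 and 76 in KY-1. Ambn changed by -0.02 in KY-1 and 3.30 in KY-2, Tuba8 by -0.29 and 2.43, Tacr1 by 0.47 and 2.94, and Kap by -0.20 and 2.23. Csn3, a milk casein gene, changed by 1.06 in KY-1 and -1.87 in KY-2, a difference of -2.93 ± 0.18 (SE, limma adjusted p = 2.19e-05). Cd36 changed by -0.08 and -2.36, but its GFP level was 3.39 in KY-1, below the array medians, where a fall would be hard to see. Tmem273 changed by 0.41 and -2.32, Cd3g by 2.52 and -0.11, and Klrh1 by 2.52 and 0.07. Limma adjusted p-values of these differences, and of that for Myb, were at most 0.00161. The count was 427 with all 12 arrays as separate replicates, 387 with trended moderation and 273 among brighter genes, and median centring gave 78 and 108 in place of 92 and 76. It fell to 88 without KY-2 GFP replicate 1 and to 109 without KY-1 GFP replicate 3.

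With the GFP vector the lines differed far more than either changed with Myb. In KY-2 the milk casein genes Csn1s1 and Csn2 were higher by 8.74 ± 0.14 and 7.31 ± 0.10 log2. The T cell genes Cd3g, Trgv1, a gamma T cell receptor segment, and Cd8a were higher by 7.68 ± 0.23, 6.26 ± 0.11 and 5.93 ± 0.11. Klhl4, the fatty acid binding protein gene Fabp5 and the lipocalin gene Lcn2 were higher by 6.67 ± 0.10, 5.89 ± 0.12 and 5.52 ± 0.13. Lower in KY-2 were Gstm5 (-6.14 ± 0.20), Eps8l3 (-5.57 ± 0.15), Pram1 (-5.21 ± 0.14), Dkkl1 (-5.04 ± 0.12), Tdrkh (-4.73 ± 0.11), Prdx4 (-4.47 ± 0.20), Tacr1 (-4.43 ± 0.10) and Ncr1 (-4.29 ± 0.19). In the line with the lower level these 16 genes stood between 3.47 and 5.58, mostly below the array medians and with no detection call, so the sizes of their differences are uncertain. Limma adjusted p-values were at most 2.73e-08 (n = 2 replicates per line), and the GFP arrays of both lines did not overlap for these 16 genes, chosen by size of difference.

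Between the lines 2718 genes were higher and 3039 lower in KY-2, 5757 in all or 28.9% of genes, and 2716 differed at least 1.5-fold. With all 12 arrays as separate replicates the total was 7069, and median centring gave 3081 higher and 2218 lower.

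Of 23 oxidative phosphorylation genes 16 were higher and 0 lower in KY-2 (18 and 1 adjusted over the list alone), with Ndufv1 at 1.27 ± 0.09 and Atp5d at 0.95 ± 0.08 (camera adjusted p = 4.69e-07). Of 28 G1/S genes 4 were higher and 17 lower (4 and 18 adjusted over the list alone), with Tyms, thymidylate synthase, at -0.71 ± 0.09, E2f8 at -0.84 ± 0.09 and Rrm2 higher at 0.87 ± 0.08 (camera adjusted p = 0.00157). Checkpoint and costimulatory receptors had 10 higher and 2 lower of 21, also adjusted over the list alone, with Cd28 at 5.19 ± 0.12, Tigit at 3.29 ± 0.11, Havcr2, or TIM-3, at 1.81 ± 0.15 and Icos at -1.52 ± 0.16 (camera adjusted p = 0.00157). ILC3 genes, typical of innate lymphoid cells of type 3, had 0 higher and 5 lower of 11, also adjusted over the list alone, with the lymphotoxin gene Lta at -1.47 ± 0.10 and Ccr6 at -1.37 ± 0.17 (camera adjusted p = 0.0282). Each of these 4 lists had an adjusted p = 0.376 with an estimated correlation, and the ILC3 call was lost without KY-1 GFP replicate 3 (adjusted p = 0.0578).

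Of 30 NK receptors and adaptors 12 were higher and 12 lower in KY-2, or 12 and 14 adjusted over the list alone (camera adjusted p = 0.979, upward; median -0.178, mean 0.087). The inhibitory receptor gene Klrc1, or NKG2A, was higher by 4.10 ± 0.13 and Crtam by 3.38 ± 0.13, while Klri1 was lower by a log2 difference of -4.24 ± 0.14. Of 22 cytotoxic effectors 6 were higher and 7 lower (6 and 8 adjusted over the list alone), with Prf1 at 2.26 ± 0.10, Ifng at 2.27 ± 0.10 and Gzmd at -2.30 ± 0.10 (camera adjusted p = 0.979, downward; median 0.048, mean -0.070). Of 12 chemokines 6 were higher and 2 lower (6 and 3 adjusted over the list alone), with Ccl5 at 3.11 ± 0.19, Ccl1 at 2.35 ± 0.14, Ccl3 at 2.28 ± 0.13 and Xcl1 at 2.01 ± 0.10 (camera adjusted p = 0.0535). The transcription factor genes Eomes and Zeb2 were higher by 2.44 ± 0.12 and 2.54 ± 0.15. Of 18 T cell markers 5 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.133), with Cd3g, Cd8a and Cd28 far higher and Skap1 at -1.06 ± 0.08.

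**Figure D4:**
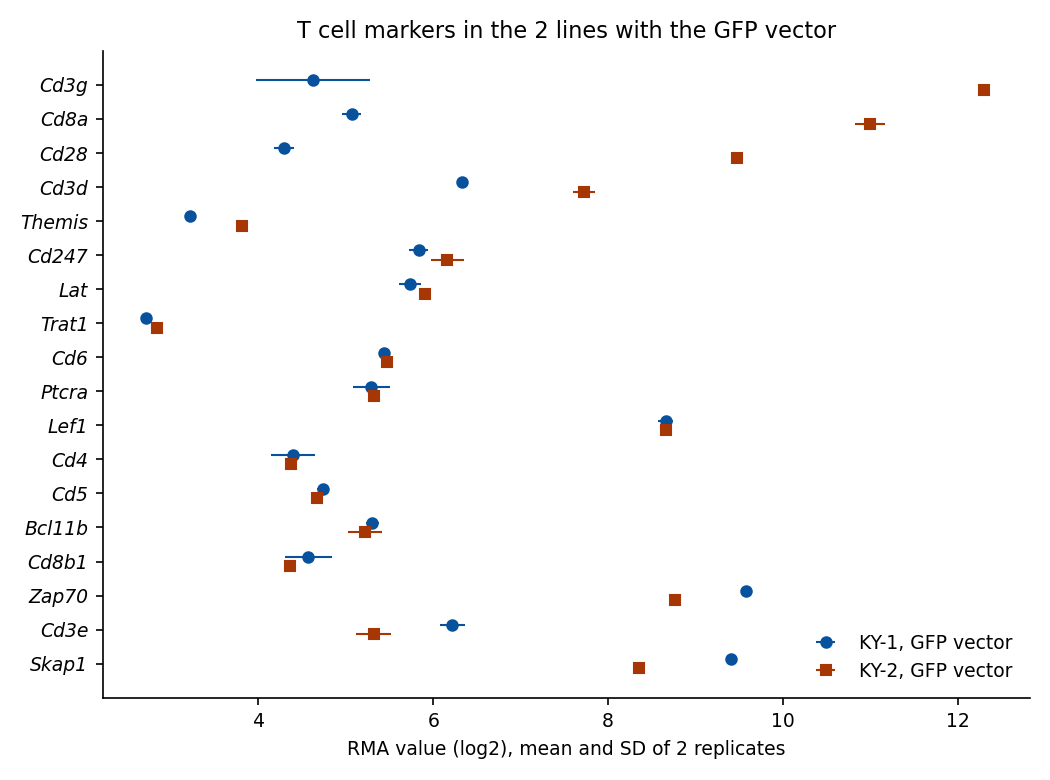
Log2 RMA level of 18 T cell markers in KY-1 (circles) and KY-2 (squares) with the GFP vector, as mean and SD of 2 replicates. Cd3g and Cd28 are near 12.3 and 9.48 in KY-2 against 4.62 and 4.29 in KY-1, while Cd3e, Zap70 and Skap1 are lower in KY-2.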

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

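The count of other splits was planned before its result was seen; the tests of array scaling, of the KY-1 array sets, of the share of NK cells and of T cells were chosen after.

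For 168 genes the Myb effect differed between lines by the limma test of the difference itself. Among genes named above, the effect in KY-2 minus that in KY-1 was 3.31 log2 for Ambn, 3.11 for Myb, 2.72 for Tuba8, 2.47 for Tacr1 and 2.42 for Kap. It was 1.86 for Ncr1, 1.45 for Ifitm1, 1.30 for Mgst2, 1.29 for Plac8 and 1.16 for B3galt2. It was -0.75 for Ccl4, -1.73 for Plek, -1.82 for Nt5e, -1.93 for Mcpt8, -1.99 for Crtam and -2.21 for Itgax. It was -2.28 for Cd36, -2.45 for Klrh1, -2.63 for Cd3g, -2.74 for Tmem273 and -2.93 for Csn3. Some genes had little signal to lose in 1 line. With GFP, Ncr1 stood at 5.43 ± 0.50 (SD, n = 2) in KY-2, near the array medians. In KY-1 Cd36, Crtam and Plek stood at 3.39, 4.64 and 4.68, below them. A fall there would be hard to see, so these 4 differences may reflect the starting level.

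At the preset correlation, 13 gene lists also differed between lines. Means of the KY-2 minus KY-1 effect were 0.213 for ILC2 and type 2 genes, 0.204 for amino acid response, 0.148 for G2/M, 0.137 for G1/S and 0.133 for cholesterol synthesis genes. They were -0.085 for oxidative phosphorylation, -0.101 for endoplasmic reticulum chaperones, -0.112 for checkpoint receptors, -0.124 for p53 targets and -0.126 for glycolysis. They were -0.218 for immediate early genes, -0.225 for cytotoxic effectors and -0.260 for mature NK cell markers (median -0.032). By limma 0 members were called in the amino acid, cholesterol, chaperone, G1/S, G2/M, glycolysis, oxidative phosphorylation and p53 lists. For G1/S 0 of 28 had an unadjusted p under 0.05. The cytotoxic and mature NK lists each had 1 member called more positive and 4 more negative in KY-2. With an estimated correlation camera called 0 of the 13 lists (lowest adjusted p = 0.377, 2 lists at an unadjusted p under 0.05), and fry called 0. Of 19 other settings, the ILC2 and p53 calls were lost in 11, the chaperone call in 10 and the checkpoint call in 9. Oxidative phosphorylation was lost in 8, glycolysis and mature NK markers in 5 each and cholesterol synthesis in 4. The amino acid, G1/S, G2/M, immediate early and cytotoxic calls were lost in 0.

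Among 13767 probe sets with no single gene symbol, which the comparisons above did not use, 8 differed between vectors in the averaged contrast, 3 higher and 5 lower with Myb.

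The 619 genes called in the averaged contrast were set against other splits of the 10 replicates, 2 against 3 within each line. Of the 100 splits 1, the real one, gave as many genes, and the highest other split gave 106. The other splits put the vector difference into the spread, which lowers their counts, and 1 in 100 is the smallest share possible. No other division of these replicates gave the count, but chance is not excluded by this.

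The lower means of the NK receptor and chemokine lists with Myb, which rest on a minority of called members in each line and lose their calls with an estimated correlation (KY-1 adjusted p = 0.301 and 0.291, KY-2 0.221 and 0.0983), were weighed against technical explanations. Uneven array scaling before RMA could not be tested, since RMA normalizes between arrays, and the array medians of 5.31 to 5.42 follow that step. A further scaling bears only on unevenness left after RMA. The averaged mean of the NK receptor list was -0.259 or lower after median centring and after a second quantile normalization. That of the chemokine list was -0.411 or lower in all 19 alternative settings, both scalings included. With the 2 sets into which KY-1 arrays fell as a block, the KY-1 mean of the NK receptor list was -0.270. Both vectors had arrays in each set, so the block could move this mean little and cannot decide on the sets as a source. KY-2, which has no such sets, had a mean of -0.270 too. The chemokine list was not weighed in this way. A smaller share of NK cells would lower abundant NK genes alike. In the average, 14 such genes, among them Gzmb, Nkg7 and Klrd1, had a median change of -0.068 (bootstrap 95% interval -0.194 to -0.027). Of these Klre1 (-0.33) and Ctsw (-0.26) were called lower. In KY-2 the 14 genes ran from Klrd1 at -0.362 and Klre1 at -0.34 to Gzmb at -0.045 and Fcer1g at 0.028. Most were below 0, with Klra5 at -0.153 and Hcst at -0.142 in the middle of the order. The receptor list's median there was -0.167, close to these middle values, so the 14 genes do not argue against a fall alike in KY-2. A loss of NK cells large enough to lower these genes as far as Cd226 or Fcgr3 is thus argued against in the average. The receptor list's averaged median was -0.17, inside the interval above. The test therefore cannot separate the shift of most receptors from a smaller loss. Some of the 14 genes, such as Klrd1 and Klre1, also stand in the receptor list, and KY-2 was not tested alone. Bright probe sets may also be compressed. What stays open includes a response to Myb, as a hypothesis, and outgrowth of vector-carrying cells that differed beforehand, which was not tested. A difference in culture, sorting or array handling shared by the replicates of a vector stays open too and was not tested.

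The T cell genes Cd3g, Cd8a, Cd28 and Trgv1 in KY-2 could come from T cells in the cultures. Such cells would bring their other abundant transcripts, but the median difference between lines over 18 T cell markers was 0.031 (bootstrap 95% interval -0.071 to 0.455). Beside the genes above, Cd3d and Themis were higher in KY-2 by 1.39 and 0.585 (limma adjusted p = 5.8e-06 and 0.0217), while Cd3e, Zap70 and Skap1 were lower by log2 differences of -0.897, -0.813 and -1.06. The test replaced, after its first value was seen, a version that had left out Cd3g, Cd8a and Cd28. A hypothesis left open is that KY-2 itself transcribes part of the T cell programme, since the lines are the groups of the design.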

How the results depend on the processing

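The averaging of close arrays, the form of the replicate block, the KY-1 array sets the test of lists on the difference between lines and the overlap of calls from separate fits were chosen after seeing the data, while the 12-array fit was the design fixed beforehand. All 62 results of genes named by rank kept their direction and call in every setting in which they were tested; the filter on dim genes removed some. Genes named as list members are outside these, and some lost their call in part of the settings, among them averaged Serpinb9b in 12 of 19, Birc3, Btg2 and Ccr7 in 9, Cebpb in 8 and Etv6 in 5. In KY-2 Slc7a5 lost its call in 10 of 20 and Asns, Tigit and Sesn1 in 7, in KY-1 Ifng in 6 and Ccl5 in 4, and the difference of Ccl4 between lines in 10 of 19. Trended moderation called 503, 897, 1043 and 387 genes in KY-1, in KY-2, averaged and for the difference between lines. All 12 arrays as separate replicates called 823 in KY-1, 1143 averaged and 427 for the difference, partly by construction, since more replicates enter. Only genes above the median probe set gave 414 in KY-1, 273 for the difference and r = 0.299 between lines. Fits of only the arrays compared called 106 in KY-1 and 346 in KY-2, with fewer arrays to estimate the spread. At least 1.5-fold changes numbered 134, 282, 142 and, between the lines with GFP, 2716.

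Leaving out 1 replicate gave 72 to 227 genes in KY-1, 182 to 556 in KY-2, 314 to 505 averaged and 88 to 142 for the difference between lines; where 1 array stayed in a group, it was assumed to vary like the others. KY-1 calls were 83 without the averaged GFP arrays 1 and 2, 72 without GFP replicate 3, 123 and 142 without Myb replicates 1 and 2, and 140 without the averaged Myb arrays 3 and 4. KY-2 calls were 182 and 284 without GFP replicates 1 and 2 and 367 without Myb replicate 3. Averaged calls were 358 and 368 without either KY-1 GFP replicate and 314 without KY-2 GFP replicate 1. Calls for the difference were 109 without KY-1 GFP replicate 3 and 88 without KY-2 GFP replicate 1.

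Replicate numbers did not pair the samples, since same-numbered GFP and Myb arrays had correlations of their deviations between -0.16 and -0.03. With the replicate block on all 12 arrays 238 genes were called in KY-2, 399 averaged, and 8 lists for the difference between lines.

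With an estimated correlation camera called 0 lists in each contrast, with 5, 2, 5, 3 and 2 at an unadjusted p under 0.05 (averaged, KY-1, KY-2, between lines with GFP, difference). Fry called 7 averaged, 2 in KY-1, 21 between the lines with GFP and 0 for the difference. Trended moderation called 7 lists in KY-1. For the difference a second quantile normalization called 6 lists, and leaving out 1 replicate 6 to 12. Myeloid cell markers in KY-1 had a median of -0.059, a mean of 0.087 and a camera direction downward (adjusted p = 0.74), and among genes above the median probe set they were called upward with a mean of 0.86 (adjusted p = 0.0167). In the main fit 1 of 21 rose in KY-1, Itgax by 2.96, and 1 fell. The filtered mean may thus rest on few genes, and the number left by the filter is not given here. Scalings moved the median of all genes by less than 0.1. The cause of these shifts was not tested unless stated. With no detection calls, signal over background does not bound the low values.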

Other observations

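The test of the Myb dose below was chosen after the effects were seen, and the lists were fixed before.

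Lists of other functions and cell types, some of whose genes also stand in the NK lists, had members that changed with Myb. Among integrins and adhesion genes 3 rose and 1 fell of 25 (7 and 5 adjusted over the list alone) in the averaged contrast, with Itga4 at 0.50 ± 0.07 and Itgb7 at 0.40 ± 0.07 beside Itgax, and the tetraspanin gene Cd63 at -0.54 ± 0.09 (camera adjusted p = 0.368). Among chemokine receptors 2 rose and 2 fell of 19, also adjusted over the list alone, with Cxcr4 and Ccr7 (0.26 ± 0.06) higher and Cxcr6 (-0.50 ± 0.06) and Cxcr3 (-0.45 ± 0.08) lower (camera adjusted p = 0.888, downward; median -0.001, mean 0.020). The anti-inflammatory cytokine gene Il10 rose by 0.82 ± 0.09, opposite to Ifng. Of the progenitor markers 2 of 21 rose, also adjusted over the list alone, the ETS factor genes Erg by 0.99 ± 0.08 and Etv6 by 0.31 ± 0.06 (camera adjusted p = 0.368), and of the mast cell and basophil markers 2 of 17 rose (3 adjusted over the list alone), Mcpt8 by 0.80 ± 0.12 and Cpa3 by 0.83 ± 0.15 (camera adjusted p = 0.44). Several of these averages came mainly from 1 line. Mcpt8 changed by 1.76 in KY-1 and -0.17 in KY-2 (limma adjusted p = 0.778), where 0 of 17 mast cell and basophil markers were called by limma, also adjusted over the list alone, and 3 had an unadjusted p under 0.05. Cxcr3 changed by -0.04 and -0.87 and Il10 by 0.37 and 1.27 in KY-1 and KY-2.

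Between the lines with GFP, 4 casein genes stood higher in KY-2. Csn1s1 and Csn2 reached 12.4 and 12.6 on the log2 scale, Csn1s2a was higher by 4.58 and Csn3 by 2.82; Csn1s2a and Csn3 here, like the cyclin and MYC genes below, were chosen after their values were seen. The D cyclin genes split, with Ccnd1 higher by 3.81 ± 0.21 and Ccnd3 lower (-1.10 ± 0.14) in KY-2 and Ccnd2 at -0.24 ± 0.09 (limma adjusted p = 0.0539). The MYC family split too, with Mycn at 2.10 ± 0.09 and Myc at -1.47 ± 0.09 in KY-2 against KY-1.

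A hypothesis was that the larger rise of Myb in KY-2 may go with larger responses of the same genes. Of 89 genes called in both lines in 1 direction, Myb left out, 53 or 59.6% changed more in KY-2 (exact binomial 95% interval 48.6 to 69.8), and their median absolute log2 change was 0.592 in KY-1 and 0.744 in KY-2. The larger median runs with the hypothesis, but the interval includes equal shares, and genes are not independent, so the hypothesis was neither borne out nor excluded. A further test, of the spread between KY-2 replicates as a source of its larger count, was drafted and dropped, since the design fixed its outcome.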
